A study of Mus musculus with 12 samples.

How the data were processed

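Gene expression was measured in 12 samples on Agilent 2-colour 4x44K mouse arrays (design 026655 per the file headers). Per the labels, the sample of each array was labelled with Cy5 and a pool of all conditions with Cy3, in the same orientation on all 12 arrays. The samples are 2 genotypes (Eng+/- and wt), 2 days (50 and 90, with no statement in the labels of what the days count) and 3 treatment levels (none named, clp, tpa). Each combination has 1 array. What clp and tpa stand for is not given in the sources used here. Each treatment level lies on a slide of its own (3 slides of 4 arrays), while both genotypes and both days lie on each slide.

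The labels conflict in several points, and the values were read by the labels and headers of the single arrays. The labels and the growth protocol call the material E14 mouse embryonic stem cells, whereas the titles name days and treatments. The series text describes wt RNA in Cy3 with dye swaps and an Axon GenePix scanner, which the array labels and headers do not show. Both wt arrays with no named treatment carry the word pool in their titles and were used as wt samples. The series text gives Feature Extraction 10.1, the processing notes of the submitters give 10.0, and the file headers give 10.7.3.1 with an Agilent scanner.

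The deposited scanner files hold foreground, background and processed signals of both channels in units of scanner intensity, together with flags for saturated, outlying and above-background spots. Per the file headers, the authors' processed signals are background-subtracted intensity values with spatial detrending, dye-normalized by linear and lowess factors. The deposited value table holds the log10 ratio of the processed Cy5 to the processed Cy3 signal, and equalled the log10 ratio in the scanner files on every spot (largest difference 0). The genome build of the probe annotation is mm9 per the file headers.

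The median foreground and background intensities were read into R 4.3.3 with the data.table package 1.17.8 and processed with limma 3.58.1 (normexp background correction with an offset of 50, loess within each array, no normalization between arrays). Mean signals had been intended before the data were examined, but the deposited files hold only median signals. Control spots had weight 0 and took no part in the loess curve, spots flagged as outliers were left out, and spots of the same probe were averaged. Of 44397 spots per array, 43020 were not controls and held 39429 probes, of which 975 were left out for an outlier flag on 1 or more arrays. A probe was tested if its Cy5 signal was well above background on at least 2 of the 12 arrays, which left 30497 probes. Probes were named by their accession through the RefSeq table (27234 named), and the probe with the highest mean intensity stood for each gene, which gave 25084 features, 17166 of them with a gene symbol. No gene coordinates are given, since the table is of another build than the files. Precision is limited by the number of arrays.

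One limma model with genotype and the 6 treatment-by-day conditions was fitted to all 12 arrays (5 residual degrees of freedom, prior degrees of freedom 4.17, eBayes with trend). It gave 7 contrasts (genotype, day over all treatments, day within each treatment, clp and tpa, each against no named treatment) and the day by treatment interaction. A second model with all 2-way interactions (2 residual degrees of freedom) gave the genotype by day and genotype by treatment interactions. All p-values are two-sided and were adjusted by the Benjamini-Hochberg method over the features tested, with a threshold of 0.05. With 1 array per group, the spread in these tests is what genotype and condition leave unexplained, and the lone arrays are assumed to vary alike. Genes at least 2-fold apart were also counted within the 6 matched genotype pairs, following the criterion in the series text, with no test. Recovery of changed genes was checked on simulated data with 100 changed genes per size: at a log2 change of 1 the model recovered 91% for genotype, 84% for clp, 80% for tpa and 49% for day in tpa, and at a log2 change of 2 at least 97% in each. False calls in these runs were 25 of 214 for genotype, 17 of 201 for clp, 15 of 194 for tpa and 14 of 160 for day in tpa, more than the threshold allows for. The simulated genes varied independently of each other, with the spreads of the fit and no shift shared by the genes of an array. Recovery in the measured arrays may therefore be lower, and a count of 0 called genes does not exclude differences of these sizes.

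Gene lists fixed before the data were examined (26 lists, 546 genes) were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a comparison. In the text, a list that passed means camera with the preset correlation. The estimated correlation was 0.647 for cell cycle, 0.623 for hair shaft, 0.613 for muscle and 0.606 for melanocyte genes. For the other lists it lay between -0.0312 (epidermis) and 0.28 (interferon response). Where it is far above the preset of 0.01, the p-values with the preset treat genes that vary together as nearly independent and are too small. Named genes follow a rule fixed before the data were examined: Eng always; the 10 largest rises and the 10 largest falls past the threshold with the same sign in every matched pair; where fewer than 10 passed, the 10 with the smallest p, applied only to genes with a symbol; and up to 4 members of each list that passed, in its direction. Genes outside the rule are named as such, and a few genes that the rule covers are withheld and not named. With median centring the median of all genes, between -0.0131 and 0.0106 after loess for the 7 contrasts, was 0.107 for genotype, 0.239 for day with no named treatment, -0.107 for day in tpa, 0.241 for clp and 0.336 for tpa, and list medians that change sign under it are given with it. Values given as ± are standard errors of the fitted log2 difference.

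Alternatives set before the data were examined were the processed signals of the authors, the deposited log10 value table, median centring instead of loess, Aquantile between arrays, Cy5 alone with quantile normalization, no filter, both channels above background on all arrays, every probe tested, eBayes without trend, and leaving out each array. Chosen after seeing the data were keeping outlier spots, leaving out the 2 wt arrays whose reference channel stood apart, leaving out the 90 d pair with no named treatment, the 50 d arrays alone, an exact sign-flip test of list medians over matched pairs, and the list tests without each array. An additive model of genotype, day and treatment served for the counts over other splits of the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.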

Results

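RNA of 12 samples was compared with a common reference pool on 2-colour arrays, with 1 array for each combination of 2 genotypes (Eng+/- and wt), 2 days (50 and 90) and 3 treatment levels (no named treatment, clp, tpa). Eng encodes endoglin, a co-receptor for ligands of the Tgf-β and Bmp families, and the series title places it in the hair follicle cycle. The median Cy5 signal of an array ranged from 166.5 to 573 and that of Cy3 from 99 to 140. Cy5 was well above background on 65.67 to 77.68% of the spots. There were no replicates within a group, so every comparison takes its spread from arrays of different conditions.

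Genes of epidermis, hair follicle and dermis were strongly expressed. All 19 measured genes of the epidermis list and 27 of 34 genes of the hair shaft and inner root sheath list were above background on all 12 arrays, and the probe of Col1a1, a dermal collagen, and 1 of 2 probes of Krt5, a basal keratin, were saturated on 12 of 12. Of 16 embryonic stem cell genes with a probe, 7 were above background on all 12 arrays and 2 on none. Pou5f1 was above background on 1 array and Zfp42 on 0, while Nanog, Dppa5a and Utf1 were above background on 12 of 12. On 1 or more arrays 17 of 34 hair shaft genes and 14 of 24 skeletal muscle genes were saturated, against 0 of the 16 embryonic stem cell genes. The labels describe the material as embryonic stem cells. These values argue against embryonic stem cells alone and go with tissue of hair-bearing skin.

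Eng was lower on the array labelled Eng+/- in 5 of the 6 genotype pairs and higher in 1. The log2 differences were -0.28 (90 d) and -1.19 (50 d) with no named treatment, -1.6 and -0.99 with clp, and -1.17 and 0.63 with tpa. Over the 6 pairs the Eng difference was -0.77 ± 0.26, which did not pass the threshold (adjusted p = 0.33). Whether the 2 arrays of tpa at 50 d were exchanged was not tested. The pair is used as labelled in each genotype result, and 0 genes passed for genotype without either of them. Where the probe lies relative to the modified part of Eng is not given in the sources used here. Eng rose with clp by 1.5 ± 0.32 (adjusted p = 0.03, higher in 4 of 4 pairs, 0.07 to 2.36), though slide and clp cannot be told apart. The Eng call was lost without any 1 of 7 arrays (both clp 50 d arrays, wt clp 90 d, both tpa 90 d arrays, and wt 90 d and Eng+/- 50 d with no named treatment), with log2 differences from 1.25 to 1.56. With tpa the Eng difference was 0.47 ± 0.32 (adjusted p = 0.36, higher in 3 of 4 pairs). Between 90 d and 50 d Eng differed by -1.41 ± 0.45 in clp (adjusted p = 0.32, lower in 2 of 2 pairs), by 1.02 ± 0.45 in tpa (adjusted p = 0.87, higher in 2 of 2) and by 0.11 ± 0.45 with no named treatment (higher in 1 of 2, -0.18 to 0.41 without single arrays). None of these passed, and their mean of -0.09 ± 0.26 joins opposite signs.

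**Figure D1:**
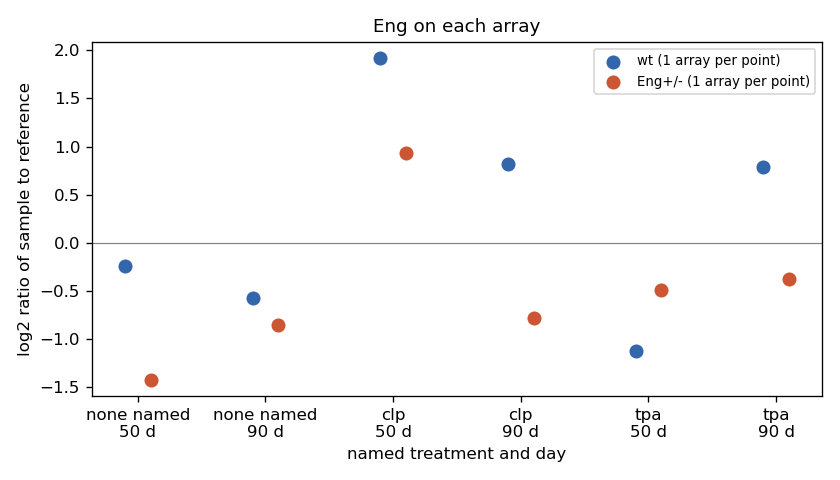
Eng on each of the 12 arrays as the log2 ratio of sample to reference pool (y axis), by treatment and day (x axis), wt in blue and Eng+/- in orange, 1 array per point. The wt point lies above the Eng+/- point in 5 of 6 conditions and below it in tpa at 50 d.

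The genotype comparison asks which genes differ between Eng+/- and wt samples across days and treatments. The hair shaft and inner root sheath list was lower in Eng+/- (median log2 difference -1.43 over 34 genes, adjusted p = 1.31e-10), with Krt82, a hair cuticle keratin, at -1.51 ± 0.33 and Dsg4, a desmosomal cadherin of the hair shaft, at -0.93 ± 0.17, both lower in 6 of 6 pairs. With an estimated correlation the call was lost (adjusted p = 0.468). No gene of that list passed over all genes, and 7 of 34 passed, all lower, adjusted over the list alone. The hair list median was -4.65 in the 90 d pair with no named treatment, lay between -0.979 and -1.48 in 3 further pairs, and was 0.00376 (clp, 50 d) and 0.138 (tpa, 50 d) in the other two. Without either array of the 90 d pair with no named treatment it was -0.619. Over all genes, the Eng+/- array of that pair correlated most with the tpa 50 d arrays (0.957 and 0.969), against 0.682 to 0.778 with the other arrays with no named treatment. Melanocyte genes were also lower (median -0.817 over 13 genes, adjusted p = 2.53e-07, or 0.468 with an estimated correlation, with 9 lower adjusted over the list alone). Among them were Tyr, the rate-limiting enzyme of melanin synthesis, at -0.69 ± 0.18, and Mlana at -0.94 ± 0.25. The melanocyte median was -2.13 in the 90 d pair with no named treatment, the lowest of the 6 pairs, and 0.0184 in the highest, the 1 pair in which it was higher.

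Skeletal muscle genes were higher in Eng+/- (median 0.555, adjusted p = 8.6e-10, or 0.468 with an estimated correlation; higher in 5 of 6 pairs, lowest -0.153), all 23 with a positive sign, including Myoz1 at 0.91 ± 0.28 and Mybpc2 at 0.84 ± 0.26, both parts of the sarcomere. Endothelial genes were higher by a median of 0.216 (adjusted p = 0.000544, or 0.468 with an estimated correlation; higher in 6 of 6 pairs, 0.0287 to 0.463), with the transcription factors Sox17 at 0.44 ± 0.13 and Sox18 at 0.45 ± 0.13. No single muscle or endothelial gene passed, over all genes or adjusted over the list alone. Of 24 muscle genes with a probe 14 were saturated in Cy5 on 1 or more arrays. How far this changed the size of the muscle difference was not tested. Adipocyte (0.0934), fibroblast (0.141) and circadian clock genes (0.23) passed as higher and cell cycle genes (-0.197) as lower, with adjusted p between 0.0106 and 0.0374. These 4 calls were lost without single arrays, and the adipocyte median ranged up to 0.163 and the fibroblast median down to 0.0637. Adipocyte genes lost theirs without an array of the clp 50 d pair (adjusted p = 0.0805) or the tpa 90 d pair (0.0551), and fibroblast genes without the same pairs (0.264 and 0.0551). Cell cycle genes did so without the 90 d pair with no named treatment (0.338) or the clp pairs at 90 d (0.0607) and 50 d (0.264), and clock genes without the clp pairs at 90 d (0.111) and 50 d (0.135) or the tpa pair at 90 d (0.0776). With median centring the medians of endothelial, adipocyte, fibroblast, clock and cell cycle genes were 0.483, 0.393, 0.366, 0.388 and -0.054. The processed signals gave 0.352 for endothelial genes and Cy5 alone 0.174 for adipocyte genes. With an estimated correlation none of the 8 genotype lists passed (adjusted p = 0.468 to 0.699).

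**Figure D2:**
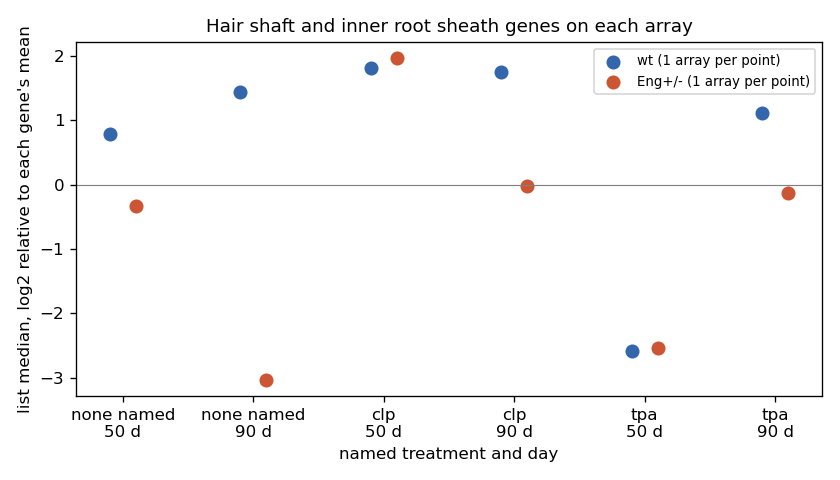
Median log2 value of the hair shaft and inner root sheath genes on each array, each gene relative to its mean over the 12 arrays (y axis), by treatment and day (x axis), wt in blue and Eng+/- in orange, 1 array per point. The lowest values are -3.04 (Eng+/-, no named treatment, 90 d), -2.54 (Eng+/-, tpa, 50 d) and -2.59 (wt, tpa, 50 d).

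Among 25084 features limma called 0 genes for genotype (3343 at an unadjusted p under 0.05, smallest adjusted p 0.3102). The genes with the smallest p, none past the threshold, had the same sign in 6 of 6 pairs. Sult1e1, an estrogen sulfotransferase, was at 0.52 ± 0.08, and Ppp1r27 at 0.81 ± 0.14. Lower were Ptgds, a prostaglandin D2 synthase, at -0.76 ± 0.13, Pla2g10, a secreted phospholipase A2, at -1.3 ± 0.24, Serpina10 at -1.19 ± 0.2, Selenov at -1.26 ± 0.21, Prss28 at -1.22 ± 0.2, Kcne1 at -0.34 ± 0.06 and Dsg4. Atxn7l2 was at -0.87 ± 0.13, with its other probe at 0.21. With median centring 222 genes passed, 25.7% of them higher.

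By the 2-fold criterion, the pairs differed widely. With no named treatment 1348 genes were at least 2-fold higher and 1119 lower in Eng+/- at 90 d, and 127 and 1015 at 50 d. With clp the counts were 517 and 1220 at 90 d and 321 and 137 at 50 d, and with tpa 45 and 326 at 90 d and 52 and 58 at 50 d. No gene was 2-fold apart the same way in all 6 pairs. Of 24 genes that were so in 5 pairs, 24 were lower, Selenov and Prss28 among them, and of 146 in 4 pairs, 140 were lower. Differences of the pairs correlated across genes between -0.14 and 0.52, and genes are not independent replicates.

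Whether the genotype difference varied with day or treatment was tested in the second model, which called 0 genes for genotype by day (899 at an unadjusted p under 0.05, smallest adjusted p 0.052) and 0 for genotype by treatment (657, smallest adjusted p 0.1674). Among the genes with the smallest p for day were Krtap14 at -4.02 ± 0.36, Krtap1-3 at -3.86, Krt84 at -3.15 and Crisp3 at -3.12. Among those for treatment, Krtap9-3 stood at 4.81 in clp and 5.36 in tpa, and Krt81 at 4.05 and 2.93, each against no named treatment. Genotype by day passed in 75 to 404 genes when 1 array was left out, and in 146 with median centring, 33 with both channels above background and 22 with every probe. With 1 array left out the second model keeps fewer than 2 residual degrees of freedom. Counts from such fits, here and for genotype by treatment, are therefore no evidence of an interaction. Genotype by treatment passed in 2 to 251 genes when 1 array was left out and in 10638 with median centring.

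The clp comparison asks what differs between the clp arrays and those with no named treatment over both days. Immune and matrix genes fell and hair, pigment and cell cycle genes rose by camera with the preset correlation, while none of these lists passed with an estimated correlation (adjusted p = 0.195 to 0.448). The largest rises were in keratin-associated protein genes, which encode the matrix of the hair shaft, with Krtap4-7 at 4.43 ± 0.71 (adjusted p = 0.017) and Krtap12-1 at 3.85 ± 0.61 (adjusted p = 0.017), and Krtap4-2, Krtap21-1, Krtap26-1, Krtap7-1, Krtap1-3, Krtap22-2 and Krtap19-9b between 4.03 and 4.42. The remaining gene among the 10 largest rises was the odorant receptor gene Olfr1134 at 4.35 ± 0.82. The largest falls were Cyp2g1, a cytochrome P450, at -3.63 ± 0.87, and Ear2 at -2.71 ± 0.22 (adjusted p = 0.0097), with Ear1 (-2.1), Ear10 (-2.03) and Rnase2a (-1.98) of the same family of eosinophil-associated ribonucleases. Il1f6, an interleukin-1 family cytokine, was at -2.33 ± 0.4, Arl4d at -2.37 ± 0.37, Cd209f, a C-type lectin, at -2.08 ± 0.24, Ctss, a lysosomal protease of antigen presentation, at -2.02 ± 0.26, and the interferon-induced Oasl2 at -1.97 ± 0.33. These genes had the same sign in 4 of 4 pairs, and whether probes of such gene families bind related transcripts was not tested.

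Among the lists, fibroblast and matrix genes fell with clp by a median of -0.839 (adjusted p = 4.18e-11; 10 of 22 lower over all genes, 19 adjusted over the list alone), with the collagen-binding proteoglycan Lum at -1.68 ± 0.26 and the collagen Col5a1 at -1.08 ± 0.17. With median centring the list median was -0.241, or -0.483 relative to all genes. Macrophage and neutrophil genes fell by -0.735 (adjusted p = 1.62e-09; 10 of 22, 14 over the list alone), with Adgre1, the F4/80 antigen, at -1.89 ± 0.2 and Csf1r, a growth factor receptor of macrophages, at -1.9 ± 0.23, whose 3 probes reached up to 0.14. Interferon response genes fell by -0.947 (adjusted p = 2.08e-08; 9 of 18, 13 over the list alone), with the interferon-induced GTPases Gbp3 at -1.34 ± 0.15 and Igtp at -1.12 ± 0.14. Lymphocyte, Langerhans and mast cell genes fell by -0.44 (adjusted p = 4.02e-06; 9 of 20, and over the list alone 11 lower and 1 higher), with the mast cell chymase Cma1 at -0.99 ± 0.17 and the T cell receptor subunit Cd3g at -1.18 ± 0.21. Endothelial genes fell by -0.276 (adjusted p = 0.00217, or 0.424 with an estimated correlation; 1 of 20, 6 over the list alone), with Ramp2 at -0.56 ± 0.14, or 0.04 under median centring. Sebaceous gland genes fell by -0.335 (adjusted p = 0.00249, or 0.424 with an estimated correlation; 6 lower and 1 higher of 16), in 3 of 4 pairs, with the lipid droplet gene Cidea at -1.41 ± 0.24 and the fatty acid elongase Elovl5 at -1.2 ± 0.21.

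Median centring moved the median of all genes in the clp comparison to 0.241, and 3 lists that fell after loess turned positive under it. Adipocyte genes had a median of -0.359 (adjusted p = 0.000453, or 0.211 with an estimated correlation; 3 of 19 lower) and 0.195 with median centring, which is -0.0464 relative to all genes, with Cebpa, a transcription factor of adipocytes, at -1 ± 0.21 and Plin1 at -0.74 ± 0.16. Epidermis genes had -0.388 (adjusted p = 0.00587, or 0.195 with an estimated correlation; 4 of 19 lower) and 0.314 with median centring, 0.0731 relative to all genes, with the keratin Krt77 at -1.6 ± 0.19 and Casp14, a protease of cornification, at -1.11 ± 0.27. Skeletal muscle genes had -0.544 (adjusted p = 0.00158, or 0.47 with an estimated correlation; 0 of 23 called, lower in 2 of 4 pairs) and 0.19 with median centring, -0.051 relative to all genes. The muscle call was lost without the wt 50 d array with no named treatment (adjusted p = 0.121), and their median was -0.941 without the Eng+/- array of that condition.

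Hair shaft and inner root sheath genes rose with clp by a median of 1.68 (adjusted p = 5.53e-08), all 34 with a positive sign, 5 past the threshold over all genes and 7 adjusted over the list alone, with Krt82 at 2.44 ± 0.41 and Dsg4 at 1.35 ± 0.2. Their median was 0.684 without the Eng+/- 90 d array with no named treatment and 2.74 without the wt array of that condition. Melanocyte genes rose by 1.03 (adjusted p = 1.46e-05; 4 of 13, 10 over the list alone), or 0.544 without the same Eng+/- array, with Mlana at 2.04 ± 0.3 and the melanosome matrix gene Pmel at 1.95 ± 0.31. Cell cycle genes rose by 0.409 (adjusted p = 2.33e-06; 4 of 30, 14 over the list alone), or 0.265 without the wt 50 d array with no named treatment, with the proliferation marker Mki67 at 1.06 ± 0.23 and the mitotic kinase Plk1 at 0.95 ± 0.21. Single arrays also moved the medians of epidermis genes (-0.171 without wt clp 90 d), sebaceous genes (-0.123 and -0.503 without the Eng+/- and the wt 90 d array with no named treatment) and lymphocyte genes (-0.676 without the latter, -0.695 without the Eng+/- 50 d array with no named treatment). With the processed signals the medians of macrophage, lymphocyte, endothelial, sebaceous and melanocyte genes were -1.26, -0.684, -0.544, -0.507 and 1.64. With median centring those of endothelial, sebaceous, melanocyte and cell cycle genes were -0.0473, -0.13, 1.68 and 0.926, and with Cy5 alone those of endothelial and epidermis genes were -0.639 and -0.142. With an estimated correlation none of the 12 clp lists passed (adjusted p = 0.195 to 0.47), while fry called 6 of them.

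**Figure D3:**
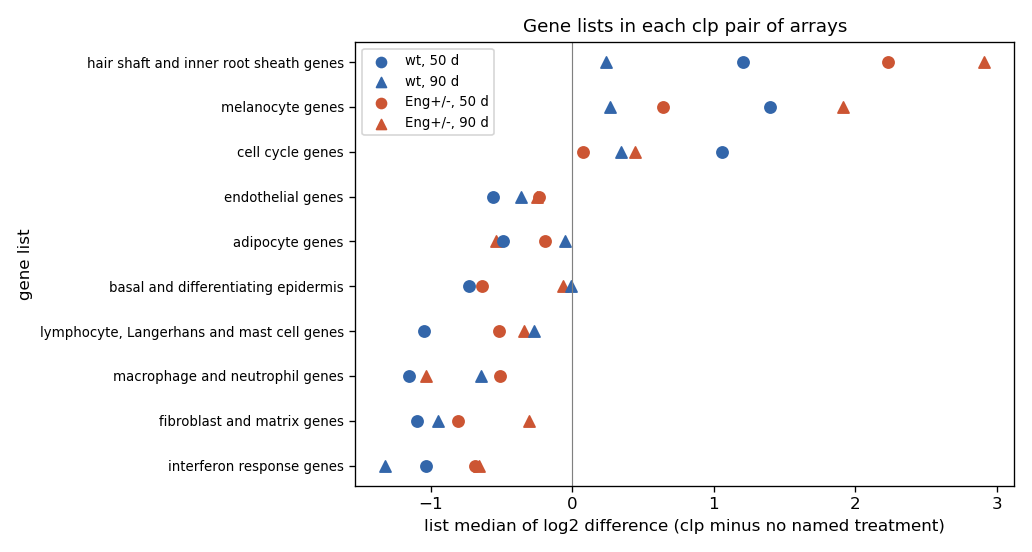
Median log2 difference between clp and no named treatment (x axis) for 10 gene lists (y axis), 1 point for each of the 4 pairs of arrays matched by genotype and day, circles 50 d and triangles 90 d, after loess. Fibroblast genes lie below 0 and hair shaft genes above 0 in 4 of 4 pairs; epidermis and adipocyte genes lie below 0 here, and their fitted medians turn positive with median centring (0.314 and 0.195).

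In all, limma called 1962 genes with clp, 1083 higher and 879 lower, 711 of them at least 2-fold apart. Of 1594 genes called with median centring 88.6% were higher, and of 6150 with Cy5 alone 50%, so the balance of directions depends on the scaling. The authors' processed signals gave 4086. The count rested on single arrays: it was 1 without wt clp 50 d, 33 without wt clp 90 d and 413 without Eng+/- clp 50 d. Among the arrays with no named treatment it was 599 without Eng+/- 50 d, 1117 without wt 50 d and 4517 without Eng+/- 90 d, and it was 785 without either tpa array of 90 d and 898 without either of 50 d. Without the 2 wt arrays whose reference channel stood apart (no named treatment 50 d and clp 90 d) it was 8. Treatment and slide cannot be told apart.

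The tpa comparison used the same arrays with no named treatment. Inflammatory cytokine and chemokine genes were higher with tpa by a median of 0.335 (adjusted p = 0.00108, higher in 4 of 4 pairs), 8 of 29 higher and 1 lower adjusted over the list alone and none over all genes. Among them the prostaglandin synthase gene Ptgs2 was at 0.81 ± 0.15 (adjusted p = 0.06), and the monocyte chemokine gene Ccl7 at 0.95 ± 0.18 (adjusted p = 0.063), both higher in 4 of 4 pairs. The list median was 0.217 without the wt 90 d array with no named treatment, 0.524 without Eng+/- tpa 90 d and 0.189 without wt tpa 90 d, and 0.6 with the processed signals and 0.673 with median centring (0.337 relative to all genes). Epidermis genes were lower by -0.351 after loess (adjusted p = 0.0303, lower in 2 of 4 pairs) and at 0.37 with median centring, 0.0341 relative to all genes, whose median moved to 0.336. With Cy5 alone it was -0.0395. The epidermis call was lost without the Eng+/- 90 d (adjusted p = 0.116) or the wt 50 d array with no named treatment (0.0972). With an estimated correlation neither list passed (adjusted p = 0.844 and 0.554), and fry called the epidermis list.

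In single genes, limma called 34 with tpa, 7 higher and 27 lower. Ccr1, a chemokine receptor of myeloid cells, rose by 0.63 ± 0.09 (adjusted p = 0.043, 4 of 4 pairs). Ttf1, a transcription termination factor, passed as higher (adjusted p = 0.033), above background on 4 of 4 tpa arrays and 0 of the 4 with no named treatment, and was at -0.13 with median centring. Nphp4, a ciliary gene, fell by 1.67 ± 0.16 (adjusted p = 0.02), Btg1b by 1.15 ± 0.09 (adjusted p = 0.0064) and the sialyltransferase gene St8sia1 by 1.14 ± 0.15. Another 7 named falls turned positive with Cy5 alone: Lrrc57 (-1.85, then 0.45), Olfr122 (-1.75, 0.91), Mdk (-1.48, 0.84), Zfp790 (-1.36, 0.15), Atxn7l2 (-1.36, 0.32), Lrrtm1 (-1.05, 0.45) and Eqtn (-0.97, 0.09). Of these, Mdk, Zfp790, Atxn7l2 and Eqtn had another probe at 0.3, 0.52, 0.02 and 0.13. Of 1037 genes called with median centring 83.6% were higher, of 457 with Cy5 alone 56.9%, and the authors' processed signals gave 0 calls.

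The tpa count also rested on single arrays. It was 4991 without the Eng+/- 90 d array with no named treatment, 4 without the wt array of that condition, 325 and 11 without the Eng+/- and wt 50 d arrays with no named treatment, and 2 without any 1 of the clp arrays. Without Eng+/- tpa 90 d it was 4, without wt tpa 90 d 18, without Eng+/- tpa 50 d 11 and without wt tpa 50 d 0.

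Day was compared within each treatment, with 2 arrays at 90 d against 2 at 50 d. In tpa, hair shaft and inner root sheath genes were higher at 90 d by a median of 2.77 (adjusted p = 3.12e-24, 26 of 34 adjusted over the list alone, 2 of 2 pairs), with Krt82 at 2.76 ± 0.57. None of the lists of this comparison passed with an estimated correlation (adjusted p = 0.168 to 0.391 over those given here and next). Melanocyte genes were higher by 2.11 (adjusted p = 4.45e-16, 10 of 13 over the list alone), with Pmel at 2.8 ± 0.44 and Mlana at 2.56 ± 0.43. Cell cycle genes were higher by 0.581 (adjusted p = 4.21e-14), all 30 with a positive sign, and Wnt pathway genes by 0.328 (adjusted p = 1.64e-06), with the Wnt-dependent transcription factor Lef1 at 1.59 ± 0.26 and Wif1 at 1.68 ± 0.33. Hedgehog pathway genes were higher by 0.413 (adjusted p = 2.08e-05), with Hhip, a target and inhibitor of the pathway, at 1.38 ± 0.32. The median was 0.961 with the processed signals, 0.799 with median centring and 0.662 with Cy5 alone. Targets of TGF-beta and BMP were higher by 0.477 (adjusted p = 0.0033), with the homeobox genes Msx1 at 0.6 ± 0.17 and Msx2 at 2.04 ± 0.6, a call lost without wt tpa 90 d (adjusted p = 0.0814), and the median was 0.193 without wt tpa 50 d and 0.299 with median centring. Stressed or hyperproliferative keratinocyte genes were higher by 0.76 (adjusted p = 1.27e-05), with the growth factor gene Areg at 1.24 ± 0.32. Dermal papilla genes were higher by 0.211 (adjusted p = 0.00292), 0.138 without Eng+/- tpa 50 d, 0.339 with the processed signals and 0.322 with median centring, with Corin, a protease of the dermal papilla, at 0.82 ± 0.26.

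Interferon response genes were lower at 90 d in tpa by -0.63 (adjusted p = 1.36e-10), with Ifi44 at -0.93 ± 0.27, and macrophage and neutrophil genes by -0.272 (adjusted p = 3e-04), with the scavenger receptor gene Marco at -0.92 ± 0.25. These medians were -0.369 without Eng+/- tpa 50 d and -0.147 without wt tpa 50 d. The macrophage median was -0.533 with median centring and -0.431 with Cy5 alone. Another 5 lists passed and lost their call without 1 or more of the tpa arrays. For single genes limma called 0 (1445 at an unadjusted p under 0.05, smallest adjusted p 0.3477) and 245 with median centring, 96.3% of them higher. It called 56 without either 90 d array with no named treatment, and 3, 21 and 16 without the Eng+/- 90 d, wt 90 d and Eng+/- 50 d tpa arrays. The smallest p went to Pnliprp1, Pla2g10 (2.59 ± 0.41), Pmel, H2-T3 (-0.78 ± 0.12), Krtap24-1, Aqp5, Ptgds (1.4 ± 0.23), Lef1, Mlana and Gnmt, of which Aqp5 had probes at 3.24 and -0.63.

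With no named treatment, interferon response genes were higher at 90 d by 0.624 (adjusted p = 4.36e-11), all 18 with a positive sign, with Ifi27l2a at 1.15 ± 0.25 and Igtp at 0.8 ± 0.2. The median was 0.984 without the Eng+/- and 0.226 without the wt 90 d array, and 1.2 with median centring (0.957 relative to all genes). Stressed keratinocyte genes were lower by -0.785 (adjusted p = 3.67e-09), with the cornified envelope genes Sprr2i at -1.53 ± 0.36 and Sprr2e at -1.12 ± 0.29. The median was -0.484 without the Eng+/- and -1.22 without the wt 50 d array. Epidermis genes were lower by -0.452 after loess (adjusted p = 2.24e-07, and 0.0463 with an estimated correlation) and at 0.155 with median centring, -0.0844 relative to all genes (-0.298 after loess without the wt 50 d array), with Krt77 at -1.09 ± 0.26 and the calmodulin-like Calm4 at -0.88 ± 0.23. With an estimated correlation every other call of this comparison was lost (adjusted p = 0.241 for interferon, stressed keratinocyte and adipocyte genes, 0.345 to 0.593 for the 7 further lists). The hair list was at -1.02 (adjusted p = 0.00122) and at 0.893 without the Eng+/- 90 d array and -2.56 without the wt 90 d array. Its direction thus rested on the former, and its call was lost without the Eng+/- 50 d array (adjusted p = 0.31). Adipocyte genes were higher by 0.366 (adjusted p = 0.000177), 0.238 without the Eng+/- 90 d array and 0.851 with median centring, with Car3, a carbonic anhydrase, at 0.69 ± 0.24. Sebaceous genes (-0.403) and macrophage genes (0.35) lost their calls without the wt 90 d array (adjusted p = 0.371 and 0.202). Their medians were -0.0499 and 0.869 with median centring. Cell cycle, Wnt pathway, clock and follicle stem cell genes passed as lower after loess, turned positive with median centring (0.208, 0.271, 0.14 and 0.274, where the median of all genes was 0.239), and lost their calls without 1 or more arrays. For single genes limma called 0 (1382 at an unadjusted p under 0.05, smallest adjusted p 0.8364), and 7 without the 2 wt arrays whose reference channel stood apart. It called 248 without the wt 90 d array, 12 without the wt 50 d array, 3 without Eng+/- 50 d and 1 without Eng+/- 90 d. Genes with the smallest p included Nova2 (-1.35 ± 0.22), Krt42, a keratin, (-1.64 ± 0.27), Epn3, Atp8b4, Myo3b, Spata31d1b, Spry2, an inhibitor of receptor tyrosine kinase signalling, (-1.84 ± 0.4), Frk and Gsdmc3.

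In clp, interferon response genes were higher at 90 d by 0.57 (adjusted p = 3.46e-05), with Igtp at 0.83 ± 0.2 and Gbp3 at 0.82 ± 0.22, and macrophage and neutrophil genes by 0.408 (adjusted p = 0.00294), with the chemokine receptor gene Ccr2 at 0.97 ± 0.26. The interferon median was 0.333 without wt clp 50 d. The macrophage call was lost without wt clp 90 d (adjusted p = 0.12) or wt clp 50 d (0.651), and its median was 0.819 without Eng+/- clp 50 d. Hair shaft and inner root sheath genes were lower by -1.12 (adjusted p = 5.63e-05), a call lost without Eng+/- clp 50 d (median -0.172; -1.84 without wt clp 50 d, -0.6 with Cy5 alone), and melanocyte genes by -0.7 (adjusted p = 0.00121), with Kit, a receptor melanocytes need, at -0.57 ± 0.2. Another 7 lists passed, and each lost its call without wt clp 50 d (adjusted p = 0.0696 to 0.904). No list passed with an estimated correlation (adjusted p = 0.568). For single genes limma called 0 (3167 at an unadjusted p under 0.05, smallest adjusted p 0.2891), and the smallest p went to Mboat4 (-0.69 ± 0.09), Upk1b, Chrna4, Sptssb, Capn8, Olfr685, Slco4c1, Slc17a1, Pbp2 and Rsph6a, all lower. It called 57 without Eng+/- clp 50 d, 4 without wt clp 90 d and 1 without Eng+/- clp 90 d.

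Over the 3 treatments, inflammatory genes were higher at 90 d by a median of 0.233 (adjusted p = 4.66e-08, or 0.372 with an estimated correlation; 6 of 6 pairs, 0 of 29 genes called), with the interferon-induced chemokine Cxcl10 at 0.61 ± 0.17 and Ccl2 at 0.38 ± 0.13. Epidermis genes were lower by -0.157 (adjusted p = 0.000112, or 0.134 with an estimated correlation; 0 of 19 called), with Krt77 at -0.53 ± 0.15. With median centring the list median was -0.00762. Within treatments the epidermis median was -0.452 with no named treatment, -0.0787 in clp and 0.0854 in tpa, the last 2 not past the threshold. The inflammatory median was 0.117 without the Eng+/- 90 d array with no named treatment and 0.361 with median centring, and the epidermis median -0.0696 without Eng+/- clp 90 d. Another 4 lists passed and lost their calls without single arrays. Limma called 0 genes for day (300 at an unadjusted p under 0.05, smallest adjusted p 0.9995) and 0 for the day by treatment interaction (3433, smallest adjusted p 0.218). With 1 array left out these counts reached 13 (without Eng+/- clp 50 d) and 214 (without the wt 90 d array with no named treatment). The smallest p of the interaction included Mboat4, the ghrelin acyltransferase (-0.88 in clp and 0.34 in tpa against no named treatment), and Lef1 (-0.39 and 2.06).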

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

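The tests of a wrong label, of weak signal, of the genotype difference in hair genes, of the slide, of the share of follicle cells and of the level of the 359 genes on the wt arrays were chosen after the results were seen. Single arrays stood far from the others of their group in 10 cases among 56 groups tested. Chance gives about 1 in 20 in independent groups of like samples. These groups overlap and mix conditions. The Cy3 correlations of wt 50 d with no named treatment and of wt clp 90 d were each flagged in more than 1 group. The 10 cases can therefore not be set against that rate.

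On the Eng+/- 90 d array with no named treatment, hair shaft and inner root sheath genes were at -3.04, melanocyte genes at -1.78, far from the other 90 d arrays, and 1846 Cy5 spots were saturated, far from the other arrays with no named treatment. Weak signal is argued against by its median Cy5 of 573, the highest of the 12 arrays. RNA of a tpa sample under a wrong label cannot be told apart from the labelled sample: over 1787 genes outside the hair and melanocyte lists the array lay at 0.813 on a scale from wt 90 d with no named treatment (0) to wt 90 d with tpa (1), with the treated arrays (0.765 to 1) and apart from the other arrays with no named treatment (0 to 0.337), while clp and tpa were not separated. Its ratios correlated at 0.957 and 0.969 with the tpa 50 d arrays and at 0.781 and 0.89 with the tpa 90 d arrays. The values were 0.682 to 0.778 with the other arrays with no named treatment and 0.58 to 0.819 with clp. The tpa 50 d arrays are also the 2 other arrays with very low hair genes, and these correlations include hair genes. No correlation was computed without them, so it cannot be told whether the match is to tpa or to low hair genes. On the scale above, which leaves hair and melanocyte genes out, the tpa 50 d arrays lay at 0.789 and 0.79. A genotype difference in hair genes, with the other 5 pairs ranging up to 0.138 and 3 of them lower in Eng+/-, and a hair cycle phase that differs between samples, which was not tested, may give low hair genes too.

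On the wt 50 d array with no named treatment and the wt 90 d clp array, the Cy3 reference correlated least with the other arrays (median correlation 0.969 and 0.965), far from the arrays of their treatment and of their day, and in both pairs many genes were 2-fold lower in Eng+/-. A lower reference signal at those genes on the 2 wt arrays is argued against by their median Cy3 deviations of -0.0587 and -0.029, where -0.5 would have been needed. A genotype difference of the 359 genes lower in both pairs may remain and could not be decided: their medians in the other pairs were -0.97, -0.182, -0.662 and, in tpa at 50 d, -0.0451. The bound set before the test took a median above -0.25 in any pair as evidence against it. That was wrong for tpa at 50 d, where these genes were already low on the wt array (median -1.55 against the other wt arrays). The median of -0.182, in clp at 50 d, also lies above the bound, but it rests on 1 pair of arrays. Its standard error of 0.0425 is over the 359 genes, which are not independent replicates. It does not measure the spread between samples, so the value decides nothing.

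On the clp arrays immune and matrix genes were lower and hair genes higher than with no named treatment. The slide cannot be told apart from clp, since 0 slides hold more than 1 treatment. A larger share of follicle keratinocytes may lower the genes of 5 other cell types alike: over the 4 pairs the mean shifts were -0.788 for fibroblasts, -0.834 for macrophages, -0.351 for endothelium, -0.549 for muscle (lower in 2 of 4 pairs) and -0.319 for adipocytes. Their range of 0.515 was no larger than list labels exchanged within pairs gave (permutation p = 0.39), while fibroblast minus endothelial genes, a pair chosen after the values were seen, differed by -0.436 ± 0.127 (SE), so the share of cells is neither excluded nor shown. A clp effect on gene expression within cells stays open, untested.

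Eng+/- tpa 50 d had a median Cy3 correlation of 0.993, above the other Eng+/- arrays (0.99 to 0.991). It was flagged because their range is narrow, and its reference matched the other arrays slightly better, not worse. On wt tpa 50 d hair shaft genes were at -2.59, far from the other wt arrays, and on Eng+/- clp 90 d they were at -0.0171, far from the other clp arrays. Skeletal muscle genes were at -1.16 on wt clp 50 d, far from the other 50 d arrays. Melanocyte genes were lower at 90 d in both clp pairs and higher in both tpa pairs, medians 2.79 apart, and stressed keratinocyte genes were lower at 90 d in both pairs with no named treatment and higher in both tpa pairs, 1.51 apart; these 2 differences were not tested.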

How the results depend on the processing

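Keeping outlier spots, leaving out the 2 wt arrays with a reference apart, the 50 d arrays alone, the exact sign-flip test and the list tests without each array were chosen after seeing the data. Unless said otherwise, the cause of a change was not tested. Signal over background limits dim genes: Cy5 was above background on 65.67 to 77.68% of the spots. Saturation limits bright genes: 364 to 1846 Cy5 spots were saturated per array, with 1669 on wt and 676 on Eng+/- in clp at 50 d. On 1 or more arrays 17 of 34 hair shaft, 14 of 24 muscle and 11 of 20 adipocyte genes were saturated, so the sizes of their differences may be compressed. Aquantile leaves log ratios as they are and tests nothing.

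With the authors' processed signals, clp called 4086 genes and tpa 0, and the genes 2-fold apart were 5788 and 2167 (no named treatment, 90 d and 50 d), 4681 and 2155 (clp) and 1261 and 894 (tpa), with 2 the same way in all 6 pairs. The value table gave 4085 for clp and 0 for tpa. With median centring, genotype called 222, day in tpa 245, tpa 1037, day by treatment 313, genotype by day 146 and genotype by treatment 10638, and the 2-fold counts were 11339 and 7089 (no named treatment) and 3757 and 2218 (clp). Cy5 alone gave 6150 for clp, 457 for tpa, and 2-fold counts of 367 (no named treatment, 50 d), 3013 and 877 (clp). Both channels above background gave tpa 4 and genotype by day 33; every probe gave genotype by day 22; eBayes without trend gave tpa 4. The additive model gave clp 746 and tpa 2, outlier spots kept gave tpa 79, and the 50 d arrays alone gave tpa 0. Without the 2 wt arrays with a reference apart, day with no named treatment called 7, day in clp 4, clp 8, tpa 10 and day by treatment 5, and 4 lists passed for day in clp and 1 for tpa; fewer arrays were fitted there.

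Leaving out 1 array at a time gave 0 to 0 genes for genotype, 0 to 13 for day, 0 to 248 for day with no named treatment, 0 to 57 for day in clp, 0 to 56 for day in tpa, 1 to 4517 for clp, 0 to 4991 for tpa, 0 to 214 for day by treatment, 75 to 404 for genotype by day and 2 to 251 for genotype by treatment. The lists that passed were 5 to 10 for genotype, 5 to 9 for day, 8 to 16, 4 to 13 and 11 to 17 for day with no named treatment, in clp and in tpa, 12 to 16 for clp and 1 to 6 for tpa. With an estimated correlation 0 lists passed except 1 for day with no named treatment. Fry called 7 for clp, 1 for tpa, 1 for day with no named treatment and 0 elsewhere. The sign-flip test called 0 throughout. With 4 pairs it can give no p under 0.125, and with the 2 pairs of day within a treatment none under 0.5. With the 6 pairs of genotype and of day its smallest p is 0.03125 before adjustment over the lists. Endothelial genes for genotype and inflammatory genes for day reached it, each higher in 6 of 6 pairs. Their adjusted sign-flip p was 0.348 and 0.812. The 0 calls of this test are therefore no evidence against the lists.

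Single named genes kept direction and side of the threshold in 201 cases with the processed signals, 197 with Cy5 alone and 164 with median centring. Reversed under median centring were Eng for day (0.06), Wnt4 (0.04), Ucp1 (-0.07) and Mcm4 (0.17) for day with no named treatment, Ramp2 for clp (0.04), and Ttf1 (-0.13), Krt77 (0.02) and Krt5 (0.01) for tpa. Reversed with Cy5 alone were Pramel34 (0.56) and Lrrc57 (0.2) for day, Postn (0.04) and Dsg4 (0.14) for day with no named treatment, Osm (-0.05) for day in clp, and for tpa Lrrc57 (0.45), Olfr122 (0.91), Mdk (0.84), Zfp790 (0.15), Atxn7l2 (0.32), Lrrtm1 (0.45) and Eqtn (0.09). With 1 array left out Eng ranged from -0.37 to 0.19 for day and from -0.18 to 0.41 for day with no named treatment.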

Other observations

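The relation of Eng to hair genes and the choice of Nog were made after the values were seen. Nog, which encodes the Bmp antagonist noggin, was at least 2-fold lower on the array labelled Eng+/- in 5 of 6 pairs, at -1.91, -1.29, -1.61, -1.46 and -1.94. It stood at 0.18 in tpa at 50 d, the pair in which Eng too was not lower. That pair had the fewest genes 2-fold apart (110), and Selenov (-0.17) and Camk2a (0.05) were not 2-fold lower in it either. Nor were the hair shaft genes Krtap15 (0.56) and Krtap19-1 (1.45), and the hair list median was 0.138 there. The shared exception is therefore not particular to Nog and Eng. Nog was among 24 genes 2-fold lower in 5 pairs, and 3 of 32 sign swaps gave as many. The fitted genotype difference of Nog was -1.34 ± 0.25 and did not pass over all genes (adjusted p = 0.31), staying between -1.22 and -1.64 when 1 array was left out. As lists, the ligands, receptors and Smads of the TGF-beta and BMP families had a genotype median of -0.0377 (adjusted p = 0.734), their targets -0.101 (adjusted p = 0.0761) and Wnt pathway genes -0.126 (adjusted p = 0.0619).

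A hypothesis is that Eng follows the hair cycle phase of a sample, and may then rise and fall with hair shaft genes. Over the 9 arrays left after setting aside 3 with very low hair genes, which lie apart as a cluster, Eng and the hair list gave Pearson r = 0.81 (exact permutation p = 0.011, adjusted p = 0.022 over 2 relations) and Spearman rho = 0.85 (exact permutation p = 0.0061), with r = 0.729 without the 2 arrays farthest from the median. The 9 arrays were set apart by the measured hair list itself, and no value was computed over all 12 arrays. The p-values hold for that subset only, without the arrays lowest in hair genes. The slide was not taken into account, with no value computed within slides. Genotype and clp go along with both measures, so the relation is no evidence of a cause.

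A second hypothesis was that the arrays were sampled at different phases of the circadian clock, which could set the clock genes Dbp and Arntl against each other. Over 12 arrays Pearson r was -0.407 (permutation p = 0.19) and Spearman rho -0.336 (permutation p = 0.29), with r = -0.18 without the 2 arrays farthest from the median. The bound set before the test took any p at or above 0.05 as evidence against the hypothesis, which was wrong, since a p that misses the threshold over 12 arrays does not exclude a relation of this size; it stays undecided.

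Another hypothesis was that genes flanking Eng carry alleles of another strain, which might make them differ by genotype. The median absolute moderated t of the 100 tested genes nearest to Eng was 0.907, at percentile 26.9 of 15156 runs of 100 neighbouring genes, far below the bound set before the test. This argues only against a difference shared by most of those genes. A median over 100 genes cannot show a difference confined to a few of them, so the hypothesis is not excluded.

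Other splits of the arrays were counted for each model. For genotype, 3343 genes had an unadjusted p under 0.05, the most among 32 swaps within pairs (1 of 32 as large, next 2652). That is the smallest share 32 swaps can give, and the several split counts were not adjusted for each other, so it does not exclude chance. Of 100 splits drawn over all arrays 11 gave as many (up to 5382), so chance could not be excluded there either. Another draw gave a lower count with the same reading. For day, 31 of 32 swaps gave at least the 214 genes of the additive model (up to 4809), so chance could not be excluded. The swaps cannot tell a structure of the samples other than day from day differences of opposite sign between treatments. The hair list, for example, had a day median of 2.77 in tpa and -1.12 in clp. For clp, 2 of 35 splits gave at least the 746 genes of the additive model, so chance could not be excluded; the highest other, 815, exchanges the Eng+/- 90 d arrays with no named treatment and with clp. For tpa 1 of 35 gave at least 2 genes (highest other 0), a share under 0.05. This does not exclude chance, since the other splits mix slides and treatments within their groups, which adds to their residual spread. The real split also follows the slides, as it does for clp. The count of 34 called for tpa falls to 0 without wt tpa 50 d or with the processed signals. For genotype by day, 2 of 4 splits gave at least 899 genes (highest other 2267), too few splits for a share under 0.05. For the 24 genes 2-fold the same way in at least 5 pairs, 3 of 32 sign swaps gave as many (highest other 41), so chance could not be excluded.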
